A study of Mus musculus with 24 samples.

How the data were processed

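The 24 samples, 3 biological replicates in each of 8 groups per the series' design text, were each hybridised to 3 slides of printed clones. Sample RNA was amplified by in vitro transcription and labelled with Cy3, and the common reference with Cy5, per the labels' protocols. No array had the dyes exchanged, so a clone-specific dye effect is common to all arrays and cancels in differences between groups, but not in a single ratio.

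The deposited scanner files hold, per the file headers, the image analysis export (version 5.1) of 1 slide and 1 channel: for each spot the mean signal intensity, the median and standard deviation of the local background intensity, and a quality flag. There were 144 such files, with 532 nm for the sample and 635 nm for the reference. These intensity values had not been normalized. The deposited value table holds 1 log2 ratio of sample over reference per spot identifier and sample, normalized by the authors; limma is named in the submitters' processing notes without a version or role. Which background correction and flag rules the authors used is not given in the sources used here. The direction and log base of the table were checked against the scanner files: its slope on log2 ratios computed without background subtraction was between 0.919 and 0.973 in all samples except remaining cells of embryonic heart, sample 1, where it was 0.766. Column medians of the table lay between -0.0064 and 0.017, and it has no missing values. It was used only as an alternative.

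From the scanner files, the background was corrected with limma's normexp method (offset 50) and log2 ratios of sample over reference were normalized by global loess on each slide, with control spots at weight 0. Spots flagged 1, 3 or 6 were left out. Spots flagged as empty (2) were kept, because leaving out dim spots would remove low values. The flagged spots left out made up between 7.71% and 35.2% of the clones of a sample. Saturated spots were kept. The slides held 88 control spots (8 beta-actin and 80 named SR) and 96 blank ones, all outside the tests. Each clone was spotted once, so no averaging of spots was needed. A clone was called well above background where its signal exceeded the median background by more than 2 of the background's standard deviations.

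A group-means model over all 24 samples was fitted to each of 16808 clones with lmFit and eBayes, and contrasts were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All 8 groups share 1 estimate of the spread. Differences of enrichment between tissues were tested as interaction contrasts. Clones without a value in a group were not tested there. The software was R 4.3.3 with limma 3.58.1, statmod 1.5.0, data.table (version 1.17.8) and jsonlite 2.0.0. Simulated data had the real missing values and 1 residual spread per clone, the same for all groups. For embryonic heart, 87% of clones changed by 2 on the log2 scale and 35% of those changed by 1 were recovered, out of 100 each. There were 8 false calls among 16808 clones. Unequal spreads between groups and scan-day effects were not simulated, so these shares do not cover them.

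The files do not pair the clone identifiers with genes, and 0 of 16808 matched the reference gene table. The 21 gene lists and cell type markers fixed before the data were examined were therefore not tested, and the rule for named genes, which asked for a symbol, named none. In their place, the clone with the largest difference in each direction is given, together with 2 clones of the set shared by 4 tissues. The former were picked among clones past the threshold, with a value in all 6 samples and without overlap between the 3 values of either group. In embryonic heart 5172 of the 15558 clones tested had all 6 values. Clones outside this choice could differ more: the shared set held increases up to 4.15 in embryonic heart and 4.53 in adult brain. This choice was made after the data were examined, and the order of the clones was not worked out again under the alternatives. The average over several probes of a gene was not applicable.

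The replicate numbers were checked for pairing between the fractions of a tissue, and none was detected. The 72 slides were scanned on 16 days, and only a few days held more than 1 group. Scan day was used as a random block, and as a fixed block in embryonic heart, the only comparison whose groups shared a day on all slides. Where 2 groups shared no day, a random block cannot take out a difference between their days, so its counts are not corrected for it. The alternatives tried were no background subtraction, print-tip loess, median centring, quantile normalization of mean intensities (which leaves ratios unchanged), other rules for flags, leaving out the dimmest 33.3% of clones, an intensity trend with robust prior, fits on the groups of a comparison alone, the deposited table, the replicate block, scan day, leaving out each sample, and, added after the data were examined, a minimum of 2 values per group and scan day combined with a fit on the embryonic heart groups alone. Also added then were overlaps expected for lists independent within strata of mean intensity on each slide (30 strata over the slides), and splits that exchange samples between 2 tissues within each fraction.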

Results

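RNA from the microvascular fraction of a mouse tissue, and from the cells left over after that fraction had been taken, was profiled on printed clone arrays. The tissues were heart and skin of E18.5 embryos, and adult heart and adult brain, all from C57BL/6 mice. Each of the 4 tissues gave both fractions, so there were 8 groups of 3 biological replicates and 24 samples. Every sample was labelled with Cy3 and hybridised together with a Cy5-labelled common reference, a pool of mouse RNA that was the same on all arrays. One sample occupied 3 slides, which together carried 16808 clones besides control spots. The comparisons ask which transcripts are enriched in small vessels, and which of these depend on the organ or on age. The spots carry clone identifiers that the files do not pair with genes, so the results are given for clones, and several clones may stand for 1 gene.

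The share of clones whose sample signal lay well above background was 97.4% ± 0.857 (SD, n = 3) in adult heart microvascular samples and 97.3% ± 0.589 in adult heart remaining cells. It was 95.4% ± 0.769 in adult brain microvascular samples and 86.3% ± 6.33 in adult brain remaining cells. In the embryo it was 85.5% ± 6.47 in heart microvascular samples, 76.7% ± 3.75 in heart remaining cells and 95.2% ± 3.47 in skin remaining cells. The lowest share, 62.9% ± 5.35, belonged to the embryonic skin microvascular samples. The number of arrays limits the precision of each comparison.

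Tissue and fraction both ordered the samples. Over the 880 clones measured in all 24 samples, the first principal component held 35.3% of the variance and ran from the embryonic samples through adult heart to adult brain. The second held 16.9% and placed the microvascular samples above the remaining cells of the same tissue. Pairs of samples within a group correlated between 0.672 and 0.936 across clones, and pairs from different groups between 0.137 and 0.689. The lowest correlation within a group was between samples 1 and 2 of the embryonic heart microvascular fraction. Across groups, the embryonic heart and embryonic skin microvascular fractions had a mean correlation of 0.623, and the remaining cells of these tissues one of 0.627. For adult heart and adult brain the values were 0.608 between microvascular fractions and 0.487 between remaining cells. The microvascular and remaining fractions of one tissue correlated at 0.533 in embryonic heart, 0.498 in embryonic skin, 0.599 in adult heart and 0.518 in adult brain.

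**Figure D1:**
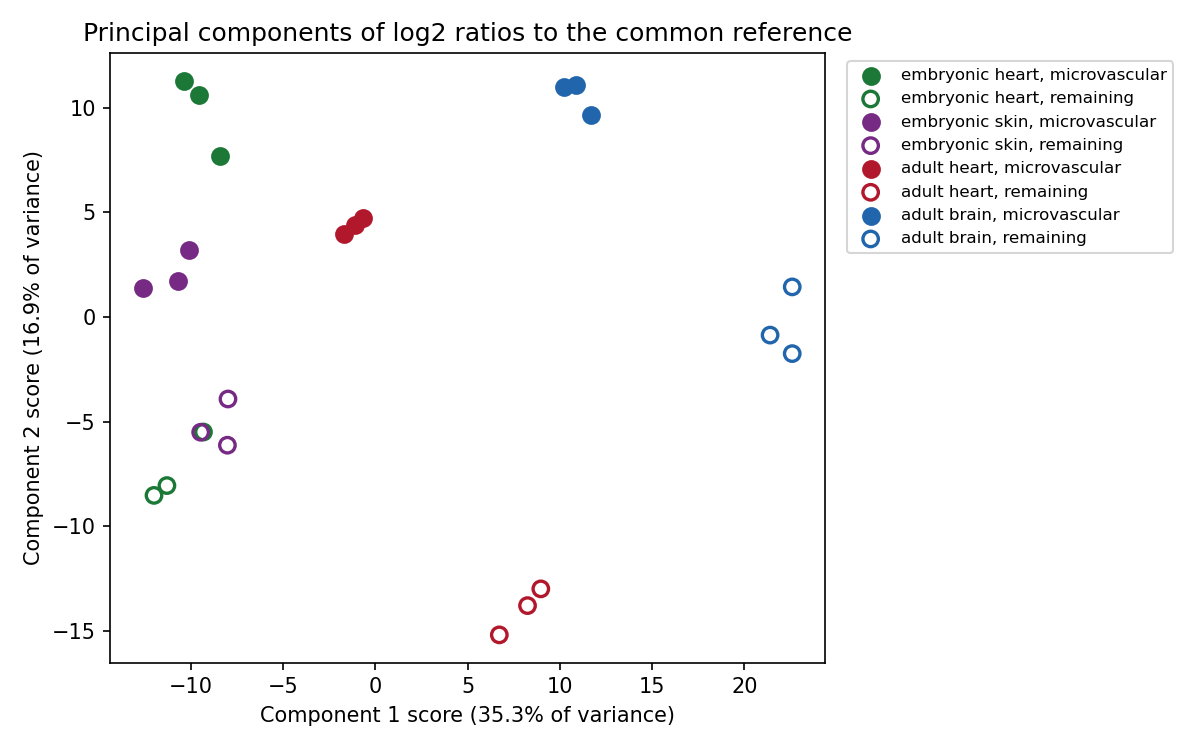
Scores of the 24 samples on the first 2 principal components of the log2 ratios to the common reference, with the share of variance on each axis label; filled circles are microvascular samples, open circles remaining cells, and colours mark the tissue. Component 1, with 35.3% of the variance, runs from embryonic samples to adult brain, and component 2, with 16.9%, separates the fractions of each tissue.

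In embryonic heart, 1233 clones were higher and 1087 lower in the microvascular fraction than in the remaining cells, out of 15558 tested. Of these, 672 were at least 2-fold higher and 668 at least 2-fold lower, and at 4-fold the numbers were 151 and 199. Among clones with all 6 values and no overlap between the groups, NOC8002C8 was named for its increase. Its log2 ratio was 4.60 ± 0.475 (SD, n = 3) in the microvascular fraction and 0.609 ± 1.00 in the remaining cells, where it was well above background in 1 of 3 samples. The difference was 3.99 ± 0.377 (SE; limma adjusted p = 7.87e-07), with a size that is uncertain because of the samples at background. It was 2.84 with every flagged spot left out and 3.24 without background subtraction, and the clone was not tested when the dimmest 33.3% of clones were left out. HUP8008F12 had the largest decrease among such clones, from 4.70 ± 0.381 in the remaining cells to -0.381 ± 0.625 in the microvascular fraction (-5.08 ± 0.304, limma adjusted p = 5.44e-10). With scan day as a random block the count was 2009 clones in place of 2320, with scan day as a fixed block it was 1076 (533 higher, 543 lower), and with only the 6 samples of the comparison in the fit it was 814 (381 higher, 433 lower). The fixed block and the fit on these samples together, a setting added after the data were examined, gave 198. One scan day held 1 sample of each fraction, and their difference correlated with that between the other samples at r = 0.586 across 5172 clones.

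In embryonic skin, 1776 clones were higher and 1689 lower in the microvascular fraction, out of 16011 tested. At least 2-fold differences numbered 941 upwards and 814 downwards, and 4-fold differences 210 and 102. Among clones with a value in all samples and no overlap between the groups, OJC8004C9 showed the largest increase. Its log2 ratio was 4.97 ± 0.362 (SD, n = 3) in the microvascular fraction against -0.456 ± 0.099 in the remaining cells (5.43 ± 0.301 SE, limma adjusted p = 2.84e-08). The clone was well above background in 2 of 3 samples of the remaining cells, and its difference was 3.93 without background subtraction, so the size is uncertain. AGO8001E19 showed the largest decrease among such clones, from 4.02 ± 0.341 to -0.65 ± 0.454 (-4.67 ± 0.404, limma adjusted p = 8.79e-07). The fractions of skin shared no scan day, so scan day and fraction cannot be told apart. With scan day as a random block 2485 clones passed.

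In adult heart, more clones were lower than higher in the microvascular fraction: 1538 rose and 2033 fell, out of 16296 tested. The imbalance was wider among large differences, with 68 clones at least 4-fold higher and 258 at least 4-fold lower. Among clones with a value in all samples and no overlap between the groups, NOC8003C20 fell the most. Its log2 ratio went from 4.26 ± 0.206 (SD, n = 3) in the remaining cells to -0.15 ± 0.735 in the microvascular fraction (-4.41 ± 0.398 SE, limma adjusted p = 5.59e-07). The largest increase among such clones was that of AAU8009P13, from -3.15 ± 0.334 to 0.0745 ± 0.833, a difference of 3.22 ± 0.751 (limma adjusted p = 0.00512). The difference of NOC8003C20 was -3.09 without background subtraction, and it was not tested when the dimmest clones were left out. The size of its decrease is therefore uncertain. The fractions of adult heart shared no scan day, and on slides 1 and 2 each was scanned on 1 day of its own. Scan day and fraction therefore cannot be told apart. With scan day as a random block 2605 clones passed.

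In adult brain, of 14639 clones tested, 2140 were higher and 2095 lower in the microvascular fraction, with 1289 at least 2-fold higher and 1262 at least 2-fold lower. At 4-fold there were 334 and 352. The balance depended on the processing: 1794 higher and 2123 lower without background subtraction, 1863 and 2053 with print-tip loess, 2217 and 2487 in the deposited table, and 2548 and 1724 with median centring. OJC8008J10 rose from -0.74 ± 0.216 (SD, n = 3) in the remaining cells to 2.89 ± 0.465 in the microvascular fraction (3.63 ± 0.387 SE, limma adjusted p = 4.59e-07). HUP8003G22 fell from 4.47 ± 0.183 to -0.0871 ± 0.0469 (-4.56 ± 0.213, limma adjusted p = 5.75e-11). The difference of HUP8003G22 was -2.95 without background subtraction, and it was not tested when the dimmest clones were left out. The size of its decrease is therefore uncertain. The brain fractions shared no scan day either, so scan day and fraction cannot be told apart here, and 3789 clones passed with scan day as a random block.

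**Figure D2:**
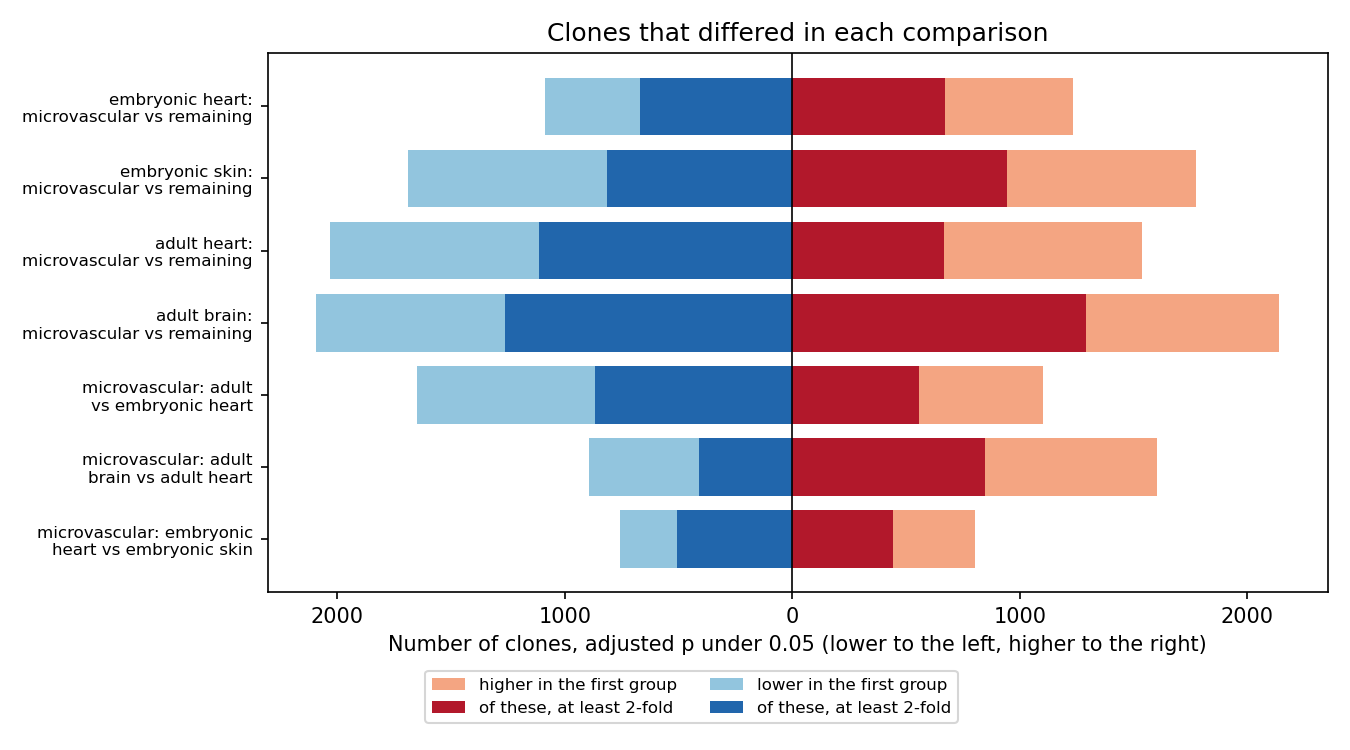
Number of clones with adjusted p under 0.05 in each of 7 comparisons, lower in the first-named group to the left of 0 and higher to the right; pale bars give all such clones and dark bars those that differed at least 2-fold. Adult brain has the longest bars, with 2140 clones higher and 2095 lower, and the embryonic heart against embryonic skin comparison the shortest, with 804 and 757.

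A set of 116 clones was higher in the microvascular fraction of all 4 tissues, out of 12809 clones tested in each of them. Lists of the same lengths that were independent of each other would share 1.77 clones, or 4.93 when independent only among clones of similar intensity on the same slide, since bright clones passed more often. Another 73 clones were lower in all 4, where such lists would share 1.98 or 5.05. These expected numbers do not allow for the spread per clone that all tissues share in the fit, by which clones of small spread pass together. In the set of 116, the median log2 difference was 1.53 in embryonic heart, 1.44 in embryonic skin, 1.21 in adult heart and 1.96 in adult brain, and 50 clones were at least 2-fold higher in every tissue. Named from this set for a large smallest difference, OJC8007I16 had differences of 2.16 ± 0.27 (SE) in embryonic heart, 2.89 ± 0.27 in embryonic skin, 2.07 ± 0.27 in adult heart and 2.33 ± 0.241 in adult brain. Its call in embryonic heart was lost with scan day as a fixed block and only the groups of the comparison in the fit. HUP8009L4 had 2.46 ± 0.184, 2.02 ± 0.184, 3.00 ± 0.184 and 3.22 ± 0.206 in the same tissues. OJC8007I16 lacked a value in 1 sample each of the embryonic heart and embryonic skin microvascular fractions and of the adult heart remaining cells. HUP8009L4 lacked one in 1 sample of the adult brain microvascular fraction. These differences thus rest on fewer samples. The order of their smallest differences turned with the processing, for instance to 1.42 for OJC8007I16 and 1.95 for HUP8009L4 without background subtraction, and to 1.94 and 2.19 with median centring. The set held 68 clones when each tissue was fitted on its own samples, and 69 when at least 2 unflagged values per group were required.

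Enrichment in one tissue went with enrichment in the others, to a degree that depended on the pair. Across clones, which are not independent replicates, the log2 differences of embryonic and adult heart correlated at r = 0.40 (rho = 0.26). For adult heart and adult brain r was 0.33 (rho = 0.33), for embryonic heart and embryonic skin 0.30 (rho = 0.16), and for embryonic heart and adult brain 0.27 (rho = 0.20). The weakest pairs by r were embryonic skin with adult heart, at 0.24 (rho = 0.16), and embryonic skin with adult brain, at 0.16 (rho = 0.095). No samples were shared within any of these 6 pairs. Embryonic and adult heart had 409 clones higher in both, where lists independent among clones of similar intensity would give 163, and 533 lower in both against 186. They had 100 clones called in opposite directions, against 333 for such lists. Embryonic skin and adult brain had 497 clones higher in both, against 273, and 308 lower in both against 248. Their opposite calls numbered 421, against 521. Such lists do not allow for the common spread, by which a clone of small spread passes more easily in both tissues. That would raise opposite calls too, which lay below the numbers for such lists in all 6 pairs.

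Age was compared in the heart. Between the microvascular fractions, 1103 clones were higher and 1652 lower in the adult than in the embryo, out of 15764 tested, with 555 and 866 at least 2-fold. OJC8010P17 was higher in the adult, at 3.23 ± 0.347 (SD, n = 3) against -0.458 ± 0.417 (3.69 ± 0.289 SE, limma adjusted p = 5.45e-07). OJC8008K17 was lower, at -0.624 ± 0.366 against 3.41 ± 0.188 (-4.03 ± 0.297, limma adjusted p = 8.62e-08). The remaining cells of the heart differed with age at 4714 clones, and the age differences of the 2 fractions correlated across clones at r = 0.45 (rho = 0.38). Clones higher in the adult in both fractions numbered 572, where lists independent among clones of similar intensity would give 214, and 807 were lower in both against 319. Opposite calls numbered 131, against 537, though such lists do not allow for the common spread per clone. The enrichment itself, microvascular over remaining cells, differed between adult and embryonic heart at 1807 clones, 733 with a larger value in the adult and 1074 with a smaller one. Of the 1074, 661 were lower in the adult heart's microvascular fraction than in its remaining cells and 414 were higher in that of the embryo. The embryonic and adult microvascular samples shared no scan day, so age and scan day cannot be told apart. The count of 2755 between them was 2030 with scan day as a random block and 1325 with only their 6 samples in the fit.

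Between the adult microvascular fractions, 1604 clones were higher in brain than in heart and 895 were lower, out of 14601 tested. The balance depended on the processing: 1476 and 1247 without background subtraction, 1664 and 1338 in the deposited table, and 2550 and 1041 with median centring. HUP8007D18 was higher in brain, at 3.23 ± 0.401 (SD, n = 3) against -1.26 ± 0.455 (4.49 ± 0.319 SE, limma adjusted p = 1.98e-08). HUP8008E19 was lower, at -1.80 ± 0.104 against 4.17 ± 0.426, a difference of -5.97 ± 0.255 (limma adjusted p = 1.85e-11). The remaining cells of brain and heart differed at 4075 clones, and the organ differences of the 2 fractions correlated at r = 0.34 (rho = 0.25). Enrichment differed between brain and heart at 2418 clones, larger in brain for 1335 and smaller for 1083. Of the 1335, 902 were higher in the brain microvascular fraction than in the remaining brain cells, and 581 were lower in the heart microvascular fraction than in the remaining heart cells. A group of 210 clones did both. The 2 adult microvascular fractions shared no scan day, so organ and scan day cannot be told apart. With scan day as a random block 1882 clones passed between them, against 2499 without it. Larger values in brain made up 55.2% of the enrichment differences, and 69% when slides were centred on their median in place of loess.

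Between the embryonic microvascular fractions, 804 clones were higher in heart than in skin and 757 were lower, out of 15538 tested. NOC8007K12 was higher in heart, at 1.74 ± 0.655 (SD, n = 3) against -1.33 ± 0.848 (3.07 ± 0.355 SE, limma adjusted p = 5.69e-05), and was well above background in 2 of 3 skin samples. HUP8003H22 was lower, at -0.224 ± 0.122 against 4.71 ± 0.884 (-4.93 ± 0.476, limma adjusted p = 1.85e-06). The remaining cells of these organs differed at 2355 clones, and here the differences of the 2 fractions correlated at r = 0.049 across clones (rho = 0.011). Of the clones called in both, 82 were higher in both, where lists independent among clones of similar intensity would give 63.6, 146 were lower in both against 56, and 150 were opposite against 120. Part of this excess may come from the common spread per clone, which was not tested. Enrichment differed between embryonic heart and skin at 1837 clones, larger in heart for 964 and smaller for 873. The embryonic microvascular fractions shared no scan day, so organ and scan day cannot be told apart. The count of 1561 between these fractions depended on the model and the samples. It was 755 with scan day as a random block (345 higher, 410 lower), 110 with only the 6 samples in the fit (34 higher, 76 lower), and between 884 and 2127 when single samples were left out. The enrichment count fell to 1005 with only its own groups in the fit, 490 larger in heart and 515 smaller.

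The beta-actin spots were the only features whose identifier names a gene; beta-actin is a cytoskeletal protein often used as a loading control. Their mean log2 ratio to the reference was 1.35 ± 0.419 (SD, n = 3) in embryonic skin microvascular samples and -1.30 ± 0.143 in the remaining skin cells, a difference of 2.66 ± 0.221 (SE; limma adjusted p = 5.43e-08). The microvascular fraction was also higher in adult heart, by 0.83 ± 0.221 (limma adjusted p = 0.00897), and in adult brain, by 1.01 ± 0.221 (limma adjusted p = 0.00144). In embryonic heart the difference was 0.377 ± 0.221 and did not pass the test (limma adjusted p = 0.291). The mean of a sample was taken over 5 to 8 spots. Between microvascular fractions the adult heart lay below the embryonic heart (-1.47 ± 0.221, limma adjusted p = 9.37e-05). The embryonic heart lay below embryonic skin (-1.04 ± 0.221, limma adjusted p = 0.006), and adult brain and adult heart both had a mean of -1.16. The calls of these differences were the same without background subtraction, with print-tip loess, with median centring and under both other flag rules. So were their directions, except between adult brain and adult heart microvascular fractions, where a difference of 0.00129 became -0.077 without background subtraction and -0.00219 with every flagged spot left out. The difference in embryonic skin was 2.02 without background subtraction.

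**Figure D3:**
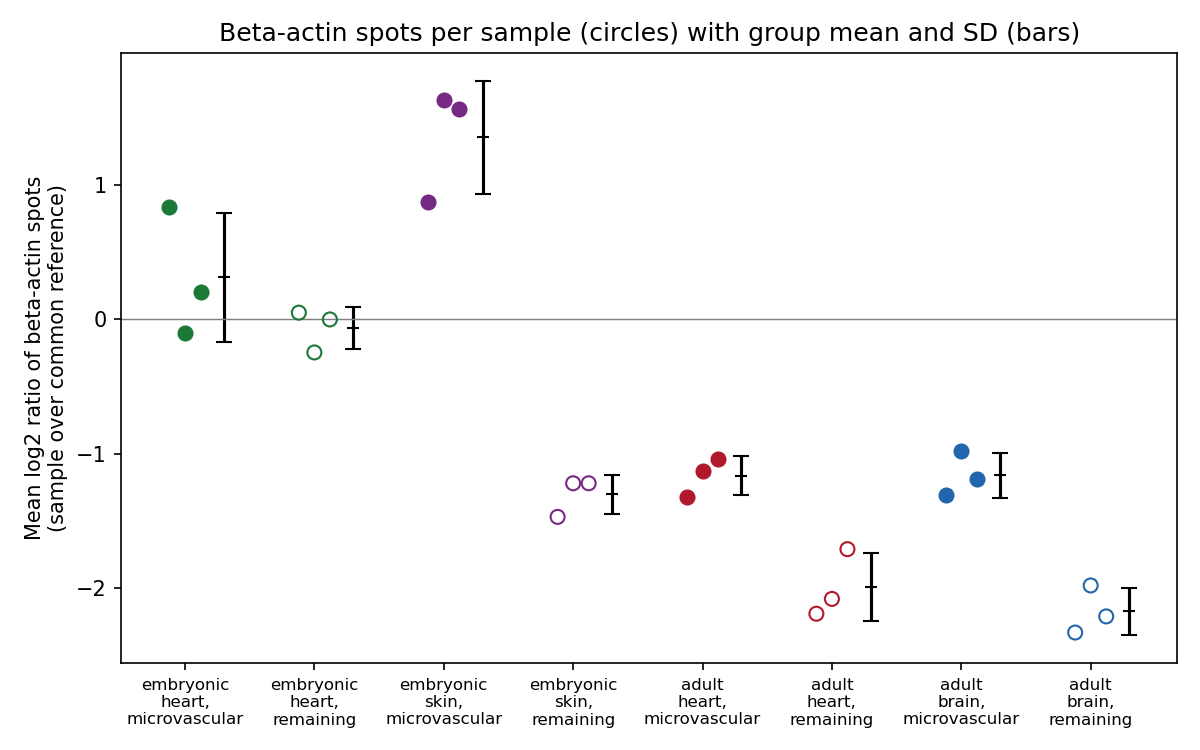
Mean log2 ratio of the beta-actin spots to the common reference in each sample (circles, filled for microvascular samples and open for remaining cells), with the group mean and SD beside them. The embryonic skin microvascular samples have a mean of 1.35, the adult brain remaining cells one of -2.17 and the adult heart remaining cells one of -1.99.

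Clones whose identifiers share a prefix were compared with the other clones of the same slides, by Fisher's exact test over 64 tests with Benjamini-Hochberg adjustment; what the prefixes stand for is not given in the sources used here. Of the 64, 29 passed, 12 with more calls than the other clones and 17 with fewer; HUP and AGO clones fill 1 slide together, so their 6 passing tests each are the same comparisons. Fisher's test takes clones as independent, which they are not, since all calls come from the same samples. Its p-values therefore do not measure variation between samples. The comparison was not matched on intensity, and dim clones passed less often: in adult heart 5.5% of the dimmest 33.3% of clones and 39.6% of the brightest. Median log2 intensities of AGO and HUP clones were 11.6 and 11.3 in embryonic heart and adult heart. They were 11.4 and 11.3 in embryonic skin, and 11 and 11.2 in adult brain. HUP clones were higher in the microvascular fraction more often than the AGO clones of the same slide in embryonic heart (10.4% against 6.47%, adjusted p = 0.0409), embryonic skin (12.8% against 6.11%, adjusted p = 0.00105), adult heart (13.6% against 6.23%, adjusted p = 0.000213) and adult brain (21.2% against 11.6%, adjusted p = 0.000604). They were also more often lower in adult heart (16.7% against 11.3%, adjusted p = 0.0214) and adult brain (18.4% against 11.6%, adjusted p = 0.014). In embryonic skin (12.4% against 8.36%, adjusted p = 0.0765) and embryonic heart (11.2% against 12.6%, adjusted p = 0.538) the shares of lower clones did not pass the test. The KSH clones, the dimmest group, were higher in 17.9% of cases in embryonic skin against 8.88% of the other clones of their slide (adjusted p = 3.05e-06), as were the DJN clones, which are not dim, at 17.2% against 8.97% (adjusted p = 4.6e-05). KSH clones were higher less often in embryonic heart (0.568% against 7.55%, adjusted p = 2.35e-08), adult heart (2.27% against 8.26%, adjusted p = 4.6e-05) and adult brain (2.27% against 11.3%, adjusted p = 1.09e-07). The shares of lower KSH clones were 1.12% against 9.05% in embryonic skin (adjusted p = 1.21e-08), 5.11% against 4.94% in embryonic heart (adjusted p = 0.913), 0.85% against 9.94% in adult heart (adjusted p = 3.67e-10) and 8.09% against 11.4% in adult brain (adjusted p = 0.138). Among the other prefixes, OJC clones were more often lower in embryonic skin (12.8% against 8.78%, adjusted p = 1.04e-09) and adult heart (13.1% against 10.3%, adjusted p = 5.45e-05), and TTO clones less often lower in adult heart (4.94% against 13.4%, adjusted p = 1.35e-05).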

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

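The tests of scan period and of samples exchanged between tissues below were chosen only after the result was seen; the others were fixed before. Groups of 3 samples were not tested for outliers.

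The enrichment of the microvascular fraction differed between adult and embryonic heart at 1807 clones, between adult brain and adult heart at 2418, and between embryonic heart and embryonic skin at 1837, each by a test of the difference itself. For these, each tissue's mean level was removed and samples were exchanged between the 2 tissues within each fraction, as equal enrichment would allow. In each case 1 of 60 splits, the real one, gave as many clones, and the highest other values were 248, 261 and 468. At this number of draws, this argues only against samples of the 2 tissues being interchangeable within each fraction. A difference between groups for another reason, such as scan day, would give the same. Mixing unlike samples widens the spread within groups, and the median of the other splits was 0, 0 and 1. The margin therefore says nothing about how many clones differ. Splits that left 1 fraction in place keep part of the real difference; where both fractions were mixed the highest values were 2, 2 and 8. Redrawing the fraction labels within tissues gave up to 1614, 2167 and 1400 clones, but stands for no enrichment at all and decides nothing about a difference in enrichment. For the 116 clones shared by 4 tissues, 1 of 60 splits with redrawn fraction labels, the real one, gave as many and the highest other was 0. This excludes only that the fraction labels are arbitrary in all tissues at once. A redrawn tissue loses nearly all its calls, so the value of 0 says nothing about whether tissues share clones beyond chance.

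For the 7 comparisons of 2 groups, the 10 splits of 6 samples are too few for a share under 0.05, and in each case only 1 split, the real one, gave as many clones. The real and the highest other counts were 2320 and 154 for embryonic heart, 3465 and 21 for embryonic skin, 3571 and 5 for adult heart, and 4235 and 179 for adult brain. They were 2755 and 38 for age, 2499 and 16 for brain against heart, and 1561 and 47 for embryonic heart against skin.

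Several clones named above differed in enrichment between tissues. Between adult and embryonic heart the log2 difference in enrichment was -3.65 for NOC8002C8, 3.47 for HUP8008F12, -2.86 for NOC8003C20, 2.49 for OJC8010P17 and -1.30 for OJC8008K17. Between adult brain and adult heart it was 2.13 for OJC8008J10, -3.81 for HUP8003G22, 4.96 for HUP8007D18 and -1.23 for HUP8008E19. Between embryonic heart and skin it was -4.52 for HUP8008F12, 2.55 for AGO8001E19 and 1.58 for NOC8007K12. The beta-actin spots differed there by -2.28. The clones were picked for a large difference that is part of these values, which are therefore no independent evidence of a difference in enrichment. Some of them rest on a group with 1 measured sample, whose spread was taken from the other groups: NOC8002C8 (adult heart microvascular fraction; -3.65 ± 0.653 SE), NOC8003C20 (embryonic heart microvascular fraction; -2.86 ± 0.689) and OJC8010P17 (remaining cells of adult heart; 2.49 ± 0.521). For AGO8001E19 and HUP8007D18 the smallest group had 2 measured samples. Some sizes also rest on samples at background and are uncertain for that reason: NOC8002C8 was well above background in 1 of 3 samples of the remaining embryonic heart cells and NOC8003C20 in 2 of 3, HUP8003G22 in 2 of 3 adult heart microvascular samples, and NOC8007K12 in 2 of 3 embryonic skin microvascular samples.

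On slide 3, 10.2% of the SR control spots lay well above background in the sample channel, against 0.217% of the blank spots.

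The differences between microvascular fractions went with those between the remaining cells for age in the heart (r = 0.45) and for brain against heart (r = 0.34). If RNA of remaining cells in the microvascular fraction were the whole cause, nearly all clones at least 4-fold higher in one tissue's remaining cells would also be higher in its microvascular fraction. Of 328 such brain clones 15.9% were at or below the heart level (95% exact binomial interval 12.1 to 20.3), and of 252 adult heart clones 13.1% were at or below the embryonic level (9.19 to 17.9). Both lie between the bounds set beforehand, so carry-over stays open. By the rule chosen, a shared scan day among the remaining cells speaks against a difference of scan period common to both fractions. For brain and heart 3 days were shared, counted over the slides. The overlap was partial, since remaining brain cells were scanned on 2 days per slide and those of heart on 1. A period difference is therefore not excluded. For age, 0 days were shared, and period and age cannot be told apart. Genes that both fractions of an organ or age express are a further candidate explanation, which was not tested.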

How the results depend on the processing

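Of the 11 counts, 5 moved by more than 1.5 times when only the groups of the comparison entered the fit: 814 for embryonic heart (2320 with all samples), 1325 for age, 110 for embryonic heart against skin microvascular fraction, 1005 for the enrichment difference between embryonic heart and skin, and 68 for the set shared by 4 tissues. In the same setting adult heart rose to 4503 (3571 with all samples), brain against heart microvascular fraction was 2512 (2499) and their enrichment difference 2535 (2418). Having fewer samples therefore did not lower every count, but its part in the falls was not tested. All 5 counts that moved include the embryonic heart microvascular fraction. Its mean correlation within the group was 0.741, against 0.865 and 0.927 in the adult heart fractions. The enrichment difference between adult and embryonic heart includes it too, yet stayed within 1.5 times. The common spread may be too small for this fraction, which would give too many calls, but the cause was not tested. With scan day as a random block the embryonic heart against skin count was 755, and with scan day as a fixed block embryonic heart gave 1076. Scan day as a fixed block together with a fit on these groups alone, added after the data were examined, gave 198 (63 higher, 135 lower). A minimum of 2 unflagged values per group, also added, gave a shared set of 69 from 6011 clones tested in all tissues. All other planned settings that change ratios left each count within 1.5 times. Leaving out single samples gave 884 (without embryonic heart microvascular sample 3), 932 (without sample 2), 901 (without embryonic skin microvascular sample 2) and up to 2127 (without embryonic heart microvascular sample 1) for embryonic heart against skin; all other counts stayed within 1.5 times. Between adult brain and heart, median centring shifted the median of all clones to 0.11 (0.037 with loess), and 69% of their enrichment differences were larger in brain, against 55.2%. The cause of these shifts was not tested.

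Same-numbered fractions of a tissue did not deviate together (12 correlations from -0.065 to 0.058, 4 of the 12 microvascular samples correlating best with their own number). No pairing by number was thus detected, which does not exclude that same-numbered fractions came from the same preparation. With the replicate block the counts were 2044, 3093, 3189 and 3923 for embryonic heart, embryonic skin, adult heart and adult brain, 1444, 2035 and 1400 for the enrichment differences, and 102 for the shared set. The clones named above kept their direction in all 395 reruns other than quantile normalization and their call in 394; OJC8007I16 in embryonic heart (2.86, adjusted p = 0.0813) lost it with scan day as a fixed block and the groups of the comparison alone. Many differences shrank by more than 1.5 times in fold terms without background subtraction: 3.93 for OJC8004C9, 2.52 for AAU8009P13, -3.09 for NOC8003C20, -2.95 for HUP8003G22, 2.81 for OJC8010P17, -3.39 for OJC8008K17, 2.62 for HUP8009L4 in adult brain, and 1.46, 1.91 and 1.42 for OJC8007I16 in embryonic heart, embryonic skin and adult heart. OJC8008J10 gave 2.82 in the deposited table, and HUP8008F12 -4.14 with scan day as a fixed block. Quantile normalization of mean intensities leaves log ratios unchanged, so it tests nothing. Gene-list alternatives and averaging over probes were not run, because the clones have no gene names here. In the sample channel 62.9% of clones lay well above background in the embryonic skin microvascular samples, and in the reference channel between 29.9% and 60.1% in the remaining cells of adult brain and between 48.8% and 58.8% in its microvascular samples.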

Other observations

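The test of scan day below was chosen only after the result was seen; the others were fixed before.

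Sample 1 of the embryonic heart microvascular fraction stood apart from its group, with correlations of 0.67 and 0.75 to samples 2 and 3, which correlated at 0.80 with each other. Its mean correlation was 0.60 with the remaining heart cells and 0.67 with the embryonic skin microvascular fraction, above those of samples 2 (0.48 and 0.58) and 3 (0.52 and 0.61). In a joint regression over 4327 clones, the slope towards the skin microvascular fraction was at least 0.17 whichever own sample served as comparison, past the bound of 0.1 set beforehand, so a share of such RNA may be present; a profile that differs in the same direction for another reason would give the same slope. The slope towards the remaining heart cells was at least 0.091, which leaves that source open. The deviations of sample 1 correlated at 0.045 with those of the remaining-cell sample scanned on the same day. No deviation common to that day was seen, but 1 pair of samples cannot exclude a scan day effect. Leaving out sample 1 of the embryonic heart microvascular fraction raised the count between embryonic heart and skin from 1561 to 2127.

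The 351 KSH clones tested had a median log2 difference of -0.352 between embryonic heart and embryonic skin microvascular fractions, with 15.1% lower and 0% higher. Without background subtraction their median was -0.223. Other clones of the same slide, matched on intensity, had a median of -0.26 (95% bootstrap interval -0.364 to -0.154). The handling of dim spots may therefore account for much of the shift in the median, although the interval reaches past the bound of -0.25 set beforehand. The quartiles were -1.271 and -0.0423 for KSH clones, against -0.687 and 0.153 for the matched clones. The KSH clones thus reached lower than the matched ones, whose share of lower calls was not counted. Position on the slide is argued against: KSH clones were spread over all 16 print blocks, and their median with print-tip loess was -0.35. No biological explanation was tested.

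In the deposited value table, slide 3 of sample 1 of the embryonic heart remaining cells correlated at 0.779 with ratios computed without background subtraction, and at 0.927 with background-corrected ones.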
